A study of Rattus norvegicus with 16 samples.

How the data were processed

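The series profiled messenger RNA in 16 brain samples of male Wistar rats, described in the design text as amygdala and in the sample labels as whole tissue lysate. Samples fell into 4 groups of 4 libraries by rearing and diet. Control samples came from undisturbed offspring on standard chow, and the HFD group from undisturbed offspring on a high fat diet. The ELS group, for early-life stress, had been separated from the dam for 3 h per day over 16 days from postnatal day 1 and received chow. The ELS-HFD group had the same separation and the high fat diet. Per the labels' protocols, animals were tested in an elevated plus maze at about postnatal day 57 and divided by diet on postnatal day 60. The labels number the samples of a group as replicates without stating that each came from its own animal, so p-values measure the spread between these samples, which may in part be technical. No litter or dam is recorded for the samples here. Those of a group may therefore be siblings and need not be independent units of the separation.

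Libraries were made from 15 ng of RNA by reverse transcription with barcoded oligo-dT primers, pooling, linear amplification and Illumina sequencing, per the labels' protocols. The submitters' processing notes name cutadapt, STAR, Picard, HTSeq, DESeq2 and the Rnor_6.0 build, without versions, roles or order. Whether the counting used strand or molecular identifiers is not given in the sources used here. Raw counts per Ensembl gene were deposited for 15580 genes, and the file header calls them raw counts. A second set of columns, headed normalized counts by the authors, is a normalized signal that equals each count divided by 1 size factor per library. For genes with at least 200 counts, the ratio of count to normalized signal deviated from a single number per library by a relative amount of at most 0.00004. The authors' deposited table also gives log2 fold changes between groups, per the file headers. It lists p-values and adjusted p-values as computed by the authors and again after a correction of the p-value distribution, whose method is not given in the sources used here. The normalized signal was used only for this check, and the authors' fold changes and p-values are printed only where their table is named. The authors' thresholds for a call included an adjusted p of at most 0.05 and a fold of at least 1.5.

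Total counts ranged from 11438086 to 23629824 per library. The 10 most abundant genes took 11.1% to 15.2% of the counts of a library. Each gene symbol and identifier was used as the table gives it, and no genomic coordinates were used here. Without a stated strand, reads of a gene and of an antisense partner cannot be told apart, and genes with near copies, such as those of the MHC, are uncertain.

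Differences between groups were tested on the raw counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Scaling used trimmed means of M values, with factors from 0.952 to 1.029. Genes were kept by filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 14208 genes. All 16 libraries entered 1 model with a mean per group, and 8 contrasts were tested. These were HFD, ELS and ELS-HFD each against control, ELS-HFD against ELS, ELS-HFD against HFD, the diet difference averaged over both rearings, the separation difference averaged over both diets, and the separation-by-diet interaction. P-values were adjusted by the Benjamini-Hochberg method over the 14208 genes of a contrast, with a threshold of 0.05. A log2 fold is followed by its standard error (SE), computed as the absolute log2 fold divided by the square root of F. Levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over the 4 libraries of a group.

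Gene lists for pathways, neuronal activity and markers of brain cell types and neighbouring regions, 36 in all with at least 5 measured members each, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The correlation between genes was preset at 0.01, and p-values were adjusted over the 36 lists of a contrast. The same test with a correlation estimated from the data and the directional fry test of limma were run beside it. Members of a list were also counted as passing over all genes and adjusted over the list alone. The level of a list in a library is the mean over its members of log2 CPM minus the gene's mean over all libraries. The lists are markers in bulk tissue and were used to describe levels, not to count cells.

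The groups, contrasts, tests, lists and most of the alternatives were fixed before the data were examined. The genes named in the text were chosen by a rule fixed at the same time. It took the genes with the smallest p among those past the threshold in each direction, up to 10 for the contrasts against control and 5 for the rest. Where few passed, genes with the smallest p filled up to 5 per direction against control and 3 elsewhere, given as values that did not pass. Symbols that are only accession-like codes were skipped. The rule added up to 4 members of each described list with the smallest p or, for cell type lists, the highest level, genes called in the authors' deposited table, and a panel of 9 genes of the stress axis, feeding and DNA methylation. Of that panel, 7 were measured, and Nr3c1 and Npy were not analysed here. Exact tests of single values used every arrangement of the libraries, two-sided, and 4 libraries against 4 allow no p below 0.0286. Full separation of 4 libraries from 4 gives that exact p, so many of the 14208 genes are expected to separate by chance. How many genes did so was not counted. Of the genes the rule gave, those named in the text for each list or contrast were picked after their values were seen, and the others are given as counts. Some genes that the rule gave are not reported here.

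Alternatives to the main choices were scaling by DESeq2 size factors, no filter on low counts, a filter of at least 50 counts in at least 4 libraries, the Wald test of DESeq2 1.42.0, the replicate number as a block, the letter at the end of the library code as a covariate, only the 8 libraries of a contrast, and leaving out each library in turn. A further 4 were chosen after seeing the data: the choroid plexus list level as a covariate, the choroid plexus and striatum list levels as covariates, leaving out the 3 libraries with the fewest choroid plexus transcripts, and leaving out the 2 libraries with the most myelin transcripts.

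The tests were checked on simulated counts drawn from the mean levels, dispersions and library sizes of these samples, with 100 genes changed by each of 1.5-fold and 2-fold among those with a mean count of at least 50. Each simulation ran on 14186 to 14198 genes. At 1.5-fold, edgeR recovered 54% for HFD against control, 65% for ELS against control, 63% for ELS-HFD against control, 60% for ELS-HFD against ELS and 74% for ELS-HFD against HFD. For the contrasts of 8 against 8 libraries the recovery was 80% for diet and 85% for separation, and for the interaction it was 25%. At 2-fold, recovery was 87% to 95% in the pairwise contrasts, 95% for diet, 96% for separation and 62% for the interaction. Simulated libraries carried no differences in tissue composition, and genes were drawn independently of each other. All changed genes of a simulation were changed together, which makes the adjusted threshold easier to pass than for a lone changed gene. Recovery of a lone change may therefore be lower than these values. Figures were drawn with matplotlib 3.10.9.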

Results

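Gene expression was measured by RNA sequencing in brain samples of male rats that had grown up with or without daily separation from the dam and later ate chow or a high fat diet. Each of the 4 groups held 4 libraries with 11438086 to 23629824 counts each, and 14208 genes were tested. The series title ties paternal early-life stress and diet to the behaviour of daughters, and these samples belong to the fathers' generation. The groups allow the effect of diet and of separation to be asked alone, together and in each other's presence. Log2 folds are given ± SE, and levels as mean ± SD with n = 4 per group.

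Levels of choroid plexus transcripts differed between libraries by far more than between groups. The choroid plexus list, 17 genes of the epithelium that secretes cerebrospinal fluid, was at -2.38 in ELS 1, -4.87 in ELS 2 and -4.93 in ELS-HFD 1 on the log2 scale relative to the mean of all libraries. The other 13 libraries lay between -0.54 and 2.19. Its most abundant member, Ttr, which encodes transthyretin, ranged from 0.275 to 12230 CPM. Oligodendrocyte and myelin genes, 21 in the list, were highest in ELS 3 at 1.08 and in ELS 4 at 0.90, and lowest in ELS-HFD 1 at -0.92. Transcripts of striatal medium spiny neurons, 16 in the list, were highest in ELS 3 at 1.18 and lowest in control 4 at -0.96.

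**Figure D1:**
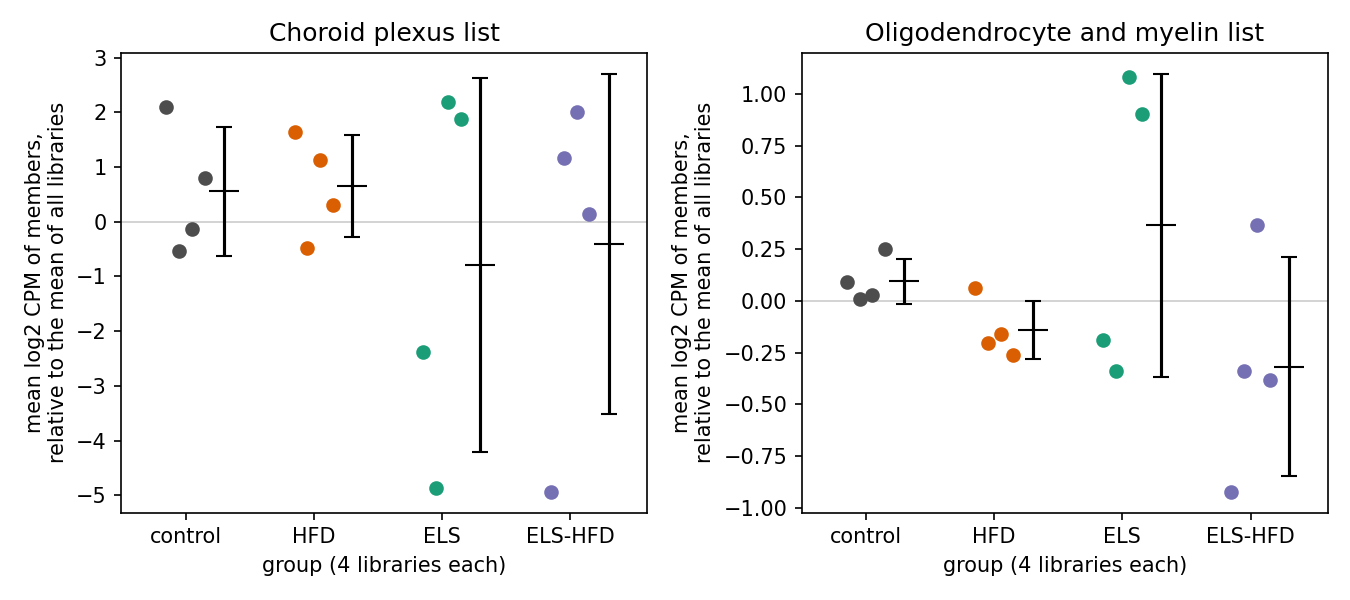
Levels of the choroid plexus list (left) and the oligodendrocyte and myelin list (right) in each library, as mean log2 CPM of the members relative to the mean of all 16 libraries, with points for libraries and bars for the group mean ± SD. ELS 1, ELS 2 and ELS-HFD 1 sit at -2.38 or lower on the choroid plexus list, and ELS 3 and ELS 4 sit at 1.08 and 0.90 on the myelin list.

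High fat diet after undisturbed rearing was compared with chow after undisturbed rearing. Samd4a (ENSRNOG00000010489), an RNA-binding protein that represses translation, had the smallest p, with 15.4 ± 1.07 CPM in control and 10.3 ± 0.482 CPM in the HFD group. All 4 HFD libraries lay below all 4 controls, with a log2 fold of -0.58 ± 0.09, and edgeR gave an adjusted p = 0.199. No gene passed in edgeR, 262 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene, Samd4a. In each contrast about 710 of the 14208 genes are expected under 0.05 by chance if genes are independent, so a count below 710 shows no excess. Genes moved together over the libraries, so a count above 710 need not be an excess either. The authors' deposited table gave Samd4a an adjusted p of 0.00112, with no gene past all of the authors' thresholds. After the authors' correction of the p-value distribution, the authors' deposited table also held Vegfa, a growth factor for blood vessels, and the sphingosine-1-phosphate receptor S1pr3 at an adjusted p of 0.0267. Their log2 folds in edgeR were -0.26 ± 0.07 for Vegfa and -0.49 ± 0.13 for S1pr3, with adjusted p = 1 for each, and all 4 HFD libraries lay below all 4 controls for both. In any pairwise contrast, chance alone separates many of the 14208 genes in this way. Such separation of a gene that did not pass adds no support. Tfap4, a transcription factor, had a log2 fold of -0.49 ± 0.14 and the phospholipid-remodelling enzyme Lpcat3 one of -0.22 ± 0.06. On the positive side stood Ammecr1 at 1.00 ± 0.23, C2cd4a at 1.31 ± 0.39 (2.00 without control 2), the sialyltransferase St6gal2 at 0.58 ± 0.17, the junctional membrane protein Jph1 at 0.42 ± 0.12 and Lonrf1 at 0.38 ± 0.11. None of these passed in edgeR.

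Of the 36 lists, camera with the preset correlation called 11 in this contrast, 2 higher and 9 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.787, or by fry. No member of any list passed over all genes or adjusted over the list alone. Of the 11 lists, only that of myelin was called in every fit that left out 1 library. All 21 myelin genes had negative log2 folds (adjusted p = 0.00233), among them Sox10, the transcription factor of the oligodendrocyte lineage, at -0.27 ± 0.15, the aspartoacylase Aspa at -0.37 ± 0.21 and the nodal matrix protein Hapln2 at -0.38 ± 0.27. The oligodendrocyte precursor list (adjusted p = 0.043), the astrocyte list (adjusted p = 0.00585) and the list of perineuronal net and matrix genes (adjusted p = 0.043) were also called lower. For these 4 lists, the adjusted p = 0.787 with an estimated correlation. Without control 4, which had the highest level of the 4 controls on all of them, the astrocyte, precursor, perineuronal net and endothelium calls ended (adjusted p = 0.842, 0.877, 0.66 and 0.641), and without HFD 4 the pericyte call ended (adjusted p = 0.136). The astrocyte members Slc4a4 and Gja1 had log2 folds of -0.25 ± 0.14 and -0.19 ± 0.11, and the matrix gene Reln one of -0.51 ± 0.24, which without control 4 were -0.14, -0.03 and -0.25. The endothelium and pericyte lists were called lower at adjusted p = 0.00483 each, and the blood list, 5 genes of red cells, at adjusted p = 0.0302. For each of these 3 lists the adjusted p = 0.787 with an estimated correlation. Cdh5 of endothelial junctions was at -0.26 ± 0.12, endomucin (Emcn) at -0.39 ± 0.21, the pericyte genes Abcc9 and Vtn at -0.39 ± 0.17 and -0.35 ± 0.15, and Alas2, the first enzyme of red cell haem synthesis, at -0.60 ± 0.34. Without HFD 1 the log2 folds were -0.59 for Aspa, -0.63 for Emcn and -0.95 for Alas2.

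Among the metabolic lists, cholesterol biosynthesis was called higher (adjusted p = 0.043) and fatty acid metabolism lower (adjusted p = 0.0369), each with adjusted p = 0.787 with an estimated correlation. Of 23 cholesterol genes, 18 had positive log2 folds, with the sterol transporter Stard4 at 0.33 ± 0.11 and Hsd17b7 at 0.26 ± 0.12. Of 23 fatty acid genes, 21 were negative, with the fatty acid binding protein Fabp7 at -0.25 ± 0.12. Leaving out control 4 turned the sign of the fatty acid call (adjusted p = 0.727). Immediate early genes, which follow neuronal activity, were called higher (adjusted p = 0.0302), with 17 of 20 positive and Egr4 and Egr1 at 0.43 ± 0.23 and 0.35 ± 0.20, or 0.18 and 0.15 without HFD 4. This call had adjusted p = 0.787 with an estimated correlation. Cytosolic ribosomal protein genes were called lower (adjusted p = 0.0369), with 46 of 59 negative and a mean log2 fold of -0.02, and had adjusted p = 0.838 with an estimated correlation. The number of lists called was 3 without HFD 4 and 6 without HFD 2. The cholesterol call ended without control 1 (adjusted p = 0.648), and the immediate early, ribosomal and red cell calls without HFD 4 (adjusted p = 0.279, 0.968 and 0.103).

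Maternal separation on chow was compared with undisturbed rearing on chow. Once accession-like symbols were skipped, the 10 genes with the smallest p, 5 per direction, were led by Galns, a lysosomal sulfatase, at -0.44 ± 0.11 and Mme, the peptidase neprilysin, at 0.61 ± 0.15. All 4 ELS libraries lay below all 4 controls for Galns and above them for Mme. The mean levels of Mme were 2.86 ± 0.340 CPM in control and 4.36 ± 0.771 CPM in ELS. Lsm8 of the U6 ribonucleoprotein was at -0.37 ± 0.10, the succinate dehydrogenase assembly factor Sdhaf3 at -0.52 ± 0.14, the ubiquitin ligase Siah1 at -0.22 ± 0.06 and the axon guidance factor Sema3e at -0.89 ± 0.24. Ankrd27 was at 0.36 ± 0.09, Cd4 at 0.80 ± 0.21, the opsin Opn3 at 0.60 ± 0.17 and Lrrc31 at 1.70 ± 0.49. No gene passed in edgeR, where the smallest adjusted p was 0.999, 472 genes had an unadjusted p under 0.05, and DESeq2 called 0. The authors' deposited table held no gene at an adjusted p of at most 0.05, before or after the correction of the p-value distribution.

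In this contrast camera with the preset correlation called 13 lists, 6 higher and 7 lower. None was called with an estimated correlation, where each of the 13 had adjusted p = 0.755, or by fry, and no member passed over all genes or adjusted over the list alone. Striatal medium spiny neuron genes were called higher (adjusted p = 6.52e-07, and adjusted p = 0.755 with an estimated correlation), with 14 of 16 positive and a mean log2 fold of 0.57. Within this list the phosphodiesterase Pde1b was at 0.53 ± 0.21, the small GTPase Rasd2 at 0.62 ± 0.27 and Ppp1r1b, the dopamine signalling protein DARPP-32, at 0.62 ± 0.32. All 21 myelin genes had positive log2 folds (adjusted p = 8.32e-06, and adjusted p = 0.755 with an estimated correlation), among them Sox10 at 0.32 ± 0.15 and the myelin glycoprotein Mog at 0.55 ± 0.27. The ELS libraries divided on these genes, with Mog at 97.1 ± 46.7 CPM in ELS against 66.5 ± 3.48 CPM in control. Without ELS 3 and ELS 4, an alternative chosen after seeing the data, the log2 folds were -0.02 for Sox10, -0.17 for Mog and -0.04 for Ppp1r1b. Without ELS 3 alone the myelin call ended (adjusted p = 0.152), and the log2 folds were 0.33 for Pde1b, 0.25 for Ppp1r1b and 0.24 for Mog. Without ELS 4 alone Sox10 was at 0.21. Without ELS 1, ELS 2 and ELS-HFD 1, also chosen after seeing the data, 23 genes passed in edgeR. That fit left only ELS 3 and ELS 4 in the ELS group, the libraries highest on the myelin list.

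Immediate early genes, circadian clock genes, microglial genes and central amygdala genes were also called higher, at adjusted p = 0.00549, 0.0108, 0.00567 and 0.00416. All 4 lists had adjusted p = 0.755 with an estimated correlation. Of the 13 lists, only the striatal, nuclear oxidative phosphorylation and red cell lists were called in every fit that left out 1 library. The microglial call ended without ELS 3 (adjusted p = 0.361), which was at 0.29 on this list while the other ELS libraries lay between -0.03 and -0.02, and without control 3 (adjusted p = 0.253). The central amygdala call ended without control 4 (adjusted p = 0.687), the immediate early call without ELS 2 or ELS 4 (0.109 and 0.133) and the clock call without control 2 (0.208). Egr4 was at 0.62 ± 0.23 and Egr1 at 0.45 ± 0.20. The clock genes Ciart and Bhlhe41 were at 0.39 ± 0.16 and 0.30 ± 0.13, and the microglial fractalkine receptor Cx3cr1 and complement gene C1qc at 0.25 ± 0.09 and 0.26 ± 0.13. Calcrl, of the central amygdala list, was at 0.25 ± 0.11. Genes of oxidative phosphorylation lay on the other side. Nuclear-encoded subunits were called lower (adjusted p = 3.26e-05), with 60 of 63 negative and Ndufa2 of complex I at -0.22 ± 0.08, and mitochondrially encoded genes were called lower (adjusted p = 0.001), with 11 of 12 negative and Mt-co2 at -0.29 ± 0.13. Both had adjusted p = 0.755 with an estimated correlation. Lower calls were also made for cytosolic ribosomal proteins (adjusted p = 0.017), interferon and MHC genes (adjusted p = 0.0128), astrocyte genes (adjusted p = 0.00723) and red cell genes (adjusted p = 0.001), again with adjusted p = 0.755 with an estimated correlation. The antiviral gene Rsad2 was at -0.73 ± 0.35, the astrocyte connexin gene Gjb6 at -0.30 ± 0.16 and Alas2 at -0.65 ± 0.35. Rsad2 was at -1.14 without ELS 3, Alas2 at -0.43 without ELS 4, and Gjb6 and Mt-co2 at -0.19 and -0.15 without control 4. The choroid plexus list was called lower (adjusted p = 0.00856, and adjusted p = 0.755 with an estimated correlation) although 16 of its 17 members had positive log2 folds in edgeR, with a mean of 0.17. Camera works on log2 CPM, on which the libraries with few transcripts weigh more than in the fit to counts. Without ELS 2 this call reversed its sign (adjusted p = 0.92). The astrocyte and mitochondrial calls ended without control 4 (adjusted p = 0.863 and 0.472), the interferon call without control 1 (0.677) and the ribosomal call without ELS 2 (0.813).

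Both exposures together were compared with neither. Samd4a again had the smallest p in edgeR, with 10.1 ± 1.21 CPM in ELS-HFD against 15.4 ± 1.07 CPM in control, a log2 fold of -0.61 ± 0.09 and an adjusted p = 0.113. All 4 ELS-HFD libraries lay below all 4 controls. Jph1, which tethers the plasma membrane to the endoplasmic reticulum, was at 0.60 ± 0.12 and the potassium channel subunit Kcng3 at 1.20 ± 0.24, each with adjusted p = 0.91 and all 4 ELS-HFD libraries above all 4 controls. Susd1 was at 0.93 ± 0.21, Lonrf1 at 0.47 ± 0.11 and the orphan receptor Gpr52 at 0.65 ± 0.16, and on the negative side the calcitonin receptor Calcr was at -1.87 ± 0.48, the mitochondrial protease Spg7 at -0.27 ± 0.07 and Lyar at -0.32 ± 0.08, each with adjusted p = 1. RT1-N2, an MHC class I gene, was at -5.73 ± 1.39 (adjusted p = 1), a value that rests on 10 counts in ELS-HFD 3, the only ELS-HFD library with any. Without ELS-HFD 3 the log2 fold was -10.18, a size that is not fixed because the remaining ELS-HFD libraries had 0 counts. The gene is also uncertain because such genes share sequence with near copies. No gene passed in edgeR, 629 had an unadjusted p under 0.05, and DESeq2 called 2, Jph1 and Samd4a. Samd4a passed without ELS-HFD 3 (adjusted p = 0.026). The authors' deposited table called Samd4a past all thresholds, and 8 genes after the correction of the p-value distribution, among them Jph1 at an adjusted p of 0.000722 and Kcng3 at 0.00105.

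Camera with the preset correlation called 9 lists here, 1 higher and 8 lower, and each of them had adjusted p = 0.783 with an estimated correlation. Fry called none, no member passed over all genes, and 3 passed adjusted over the list alone. Interferon and MHC genes were called lower (adjusted p = 1.12e-06, and adjusted p = 0.783 with an estimated correlation), with 22 of 25 negative. The immunoproteasome subunit Psmb8 was at -1.50 ± 0.43, Rsad2 at -1.07 ± 0.35, and the interferon regulatory factors Irf1 and Irf9 at -0.35 ± 0.12 and -0.28 ± 0.10. All 21 myelin genes were negative (adjusted p = 9.92e-07, and adjusted p = 0.783 with an estimated correlation), with Sox10 at -0.29 ± 0.15, Mbp, which encodes myelin basic protein, at -0.46 ± 0.30 and Myrf at -0.28 ± 0.18. Mbp was at -0.76 without ELS-HFD 3, and Myrf at -0.17 without control 4 and -0.18 without ELS-HFD 1. The central amygdala list (adjusted p = 0.0162) and the hypothalamus list (adjusted p = 0.00397) were called lower, each with adjusted p = 0.783 with an estimated correlation. Their peptide and transcription factor genes had wide errors, with Isl1 at -2.35 ± 0.78, Nts (neurotensin) at -1.16 ± 0.44, Crh (corticotropin-releasing hormone) at -0.93 ± 0.40, Gal (galanin) at -2.06 ± 0.63, Avp (vasopressin) at -2.78 ± 0.87 and Otp at -2.42 ± 0.96, or -1.35 without control 2. Levels of Gal were 6.57 ± 4.55 CPM in control and 1.61 ± 1.02 CPM in ELS-HFD.

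Lower calls in this contrast also covered ependymal genes (adjusted p = 0.0313), heat shock and unfolded protein genes (adjusted p = 0.0294), nuclear oxidative phosphorylation genes (adjusted p = 0.00047) and mitochondrially encoded genes (adjusted p = 0.0294), each with adjusted p = 0.783 with an estimated correlation. The chaperone Dnaja1 was at -0.14 ± 0.07 (-0.07 without control 1) and Mt-co2 at -0.30 ± 0.13. Without control 4 the mitochondrial call reversed its sign (adjusted p = 0.958) and Mt-co2 was at -0.16. The excitatory neuron list was called higher (adjusted p = 0.0381, and adjusted p = 0.783 with an estimated correlation), with 11 of 13 positive, the kinase Camk2a at 0.25 ± 0.14 and the vesicular glutamate transporter Slc17a7 at 0.23 ± 0.15. Camk2a ranged from 0.16 without ELS-HFD 1 to 0.42 without control 4, and Slc17a7 was at 0.13 without control 3. The number of lists called was 5 without control 3 and 14 without control 2. Only the interferon and myelin lists were called in every fit that left out 1 library. The heat shock call ended without control 1 (adjusted p = 0.794), the ependymal call without ELS-HFD 1 (0.979), the central amygdala, excitatory neuron and hypothalamus calls without control 3 (0.416, 0.207 and 0.0727) and the nuclear oxidative phosphorylation call without control 1 (0.0893).

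Among separated males, high fat diet was compared with chow. Samd4a fell by 0.72 ± 0.09 on the log2 scale, from 16.6 ± 1.28 CPM in ELS to 10.1 ± 1.21 CPM in ELS-HFD (edgeR adjusted p = 0.0153), and was lower in 4 of 4 ELS-HFD libraries than in every ELS library. It was the only gene past the test in edgeR, 882 genes had an unadjusted p under 0.05, and DESeq2 called 5, with Samd4a, Smad7, Chat and Ngfr among them. The inhibitory Smad protein Smad7 was at -0.34 ± 0.07, the glycine transporter Slc6a9 at -0.56 ± 0.13, the secretory GTPase Rab3d at 0.41 ± 0.09 and Lonrf1 at 0.48 ± 0.11, each with adjusted p = 0.648 in edgeR. The cholinergic genes Chat and Ngfr were at -3.78 ± 0.89 (adjusted p = 0.648) and -3.19 ± 0.82 (adjusted p = 0.661). Both folds rest on ELS 3 and ELS 4, at 16.8 and 6.07 CPM for Chat and 28.5 and 12.3 CPM for Ngfr, against at most 1.73 CPM for Chat and 1.57 CPM for Ngfr in ELS 1 and ELS 2. Without those libraries the log2 folds were -1.51 for Chat and -0.24 for Ngfr, an alternative chosen after seeing the data, and without ELS 3 alone Ngfr was at -2.08. The authors' deposited table had 5 genes at an adjusted p of at most 0.05 and 3 past all thresholds, and 20 past all thresholds after the correction of the p-value distribution, which included Gpr22 and Sertm1 (edgeR log2 folds 0.66 ± 0.16 and 0.95 ± 0.24).

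**Figure D2:**
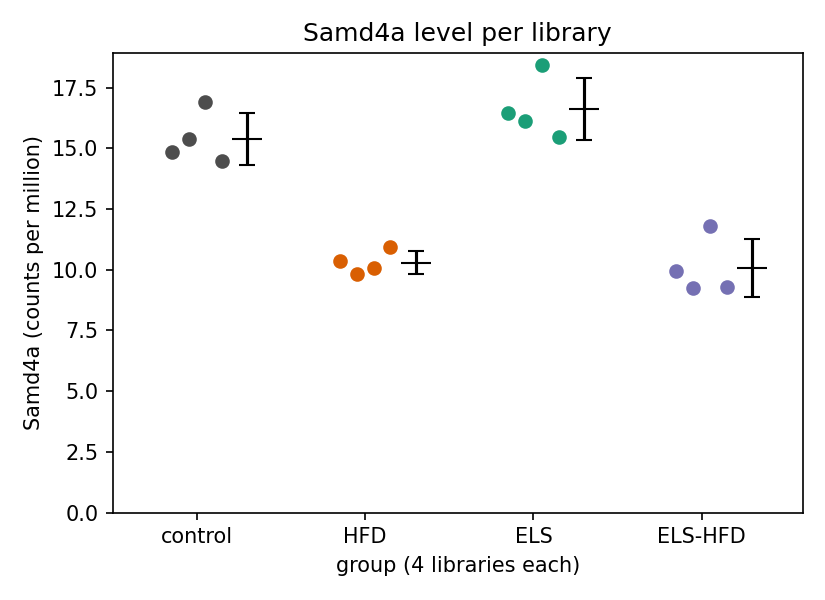
Samd4a in CPM in each library, by group, with points for the 4 libraries and bars for the mean ± SD. The means were 15.4 CPM in control and 16.6 CPM in ELS on chow, against 10.3 CPM in HFD and 10.1 CPM in ELS-HFD, and all 8 high fat libraries lay below all 8 chow libraries.

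The Samd4a call of ELS-HFD against ELS ended in a fit of only the 8 libraries (adjusted p = 0.794), with the choroid plexus and striatum levels as covariates (adjusted p = 0.0689), without ELS 3 and ELS 4 (adjusted p = 0.294), and in 6 of the 8 fits that left out 1 of its libraries. Those were Samd4a without ELS 1 (adjusted p = 0.0798), ELS 2 (0.0547), ELS 3 (0.0861), ELS-HFD 1 (0.1), ELS-HFD 2 (0.101) and ELS-HFD 4 (0.112). The log2 fold of Samd4a stayed between -0.80 and -0.67 in all 19 alternatives, those that ended the call included. With the choroid plexus level as a covariate 58 genes passed, and without ELS 1, ELS 2 and ELS-HFD 1 the count was 116, both alternatives chosen after seeing the data. The latter fit left ELS 3 and ELS 4 as the only ELS libraries.

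Camera with the preset correlation called 9 lists in this contrast, 2 higher and 7 lower, none of them with an estimated correlation or by fry. No list member passed over all genes, and 38 passed adjusted over the list alone, 19 of them among the 21 myelin genes. All 21 myelin genes were negative (adjusted p = 3.6e-18, and adjusted p = 0.483 with an estimated correlation), with a mean log2 fold of -0.75. Sox10 was at -0.61 ± 0.15, the myelin glycoprotein Mag at -0.86 ± 0.26, the sphingolipid hydroxylase Fa2h at -0.99 ± 0.30 and Hapln2 at -0.90 ± 0.27. Without ELS 3 and ELS 4 these were -0.26 for Sox10, -0.22 for Mag, -0.30 for Fa2h and -0.21 for Hapln2. All 13 central amygdala genes were negative too (adjusted p = 2.52e-07, and adjusted p = 0.483 with an estimated correlation), and 4 of them passed adjusted over the list alone. Isl1 was at -2.72 ± 0.77, Nts at -1.36 ± 0.44, Pdyn (prodynorphin) at -1.39 ± 0.47 and Crh at -1.13 ± 0.40. The broader neuropeptide list was called lower (adjusted p = 0.0254, and adjusted p = 0.639 with an estimated correlation), with 11 of 15 negative, but its member Cartpt was at 1.25 ± 0.39. Striatal genes were called lower (adjusted p = 0.000119, and adjusted p = 0.639 with an estimated correlation), with Rasd2 at -0.63 ± 0.27, or -1.02 without ELS-HFD 4. Interferon and MHC genes were called lower at adjusted p = 0.0302, and at adjusted p = 0.818 with an estimated correlation.

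Excitatory neuron genes were called higher (adjusted p = 0.0102, and adjusted p = 0.636 with an estimated correlation), with 11 of 13 positive, Slc17a7 at 0.34 ± 0.15 (0.19 without ELS 3) and the transcription factors Neurod1 and Fezf2 at 0.83 ± 0.38 and 0.47 ± 0.18. Red cell genes were called higher (adjusted p = 0.0302), while oligodendrocyte precursor genes (adjusted p = 0.0302) and pericyte and smooth muscle genes (adjusted p = 0.0362) were called lower. These 3 lists had adjusted p = 0.636 with an estimated correlation. The smooth muscle genes Tagln and Acta2 were at -0.84 ± 0.31 and -0.69 ± 0.28, and at -0.20 and -0.31 without ELS 3 and ELS 4. With the choroid plexus and striatum levels as covariates Neurod1 was at 0.12. The myelin level was 0.36 ± 0.73 in ELS and -0.32 ± 0.53 in ELS-HFD, and its difference of -0.68 had an exact permutation p = 0.143, two-sided over 70 arrangements. Without ELS 3 and ELS 4 the difference was -0.05 ± 0.27 (SE). Without ELS 1 the number of lists called was 16. Only the myelin, central amygdala and striatal lists were called in every fit that left out 1 library. The excitatory neuron and interferon calls ended without ELS 3 (adjusted p = 0.32 each), the neuropeptide call without ELS 2 (0.139), the precursor call without ELS-HFD 4 (0.129), the pericyte call without ELS 4 (0.149) and the red cell call without ELS-HFD 3 (0.216).

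Maternal separation was next examined among males on the high fat diet. B4galt4, a galactosyltransferase, had the smallest p at 0.31 ± 0.07, with 17.5 ± 0.540 CPM in ELS-HFD and 14.1 ± 0.514 CPM in HFD. The phosphatase Ctdspl2 was at 0.74 ± 0.20 and the matrix protease Adamts9 at 0.84 ± 0.23, and for all 3 genes the 4 ELS-HFD libraries lay above the 4 HFD libraries. The interferon lambda receptor Ifnlr1 was at -0.95 ± 0.25, the zinc finger gene Zfp663 at -0.89 ± 0.24 and Ddah1, which clears an inhibitor of nitric oxide synthase, at -0.31 ± 0.09. No gene passed in edgeR (smallest adjusted p = 1), 252 had an unadjusted p under 0.05, and DESeq2 called 0. The authors' deposited table held 0 genes past its thresholds, and 10 after the correction of the p-value distribution, with Ctdspl2, Ifnlr1 and Gal among them at an adjusted p of 0.0117.

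Camera with the preset correlation called 13 lists, 2 higher and 11 lower, none with an estimated correlation or by fry, and no member passed over all genes or adjusted over the list alone. Neuropeptide genes (adjusted p = 6.46e-05), central amygdala genes (adjusted p = 1.95e-05) and the stress axis list (adjusted p = 0.00824) were called lower, each with adjusted p = 0.721 with an estimated correlation. Gal was at -2.00 ± 0.63, Nts at -1.31 ± 0.43 and Crh at -1.12 ± 0.39, with Crh at 3.18 ± 1.56 CPM in ELS-HFD and 6.90 ± 0.172 CPM in HFD. Of the panel, the CRH receptor Crhr1 was at -0.47 ± 0.30, the oxytocin receptor Oxtr at -0.44 ± 0.28, the glucocorticoid receptor chaperone Fkbp5 at -0.14 ± 0.11, the leptin receptor Lepr at 0.76 ± 0.69, Bdnf at -0.16 ± 0.22 and the DNA methyltransferase Dnmt3a at -0.02 ± 0.10, each with edgeR adjusted p = 1. These folds moved when 1 library was left out. Crhr1 ranged from -0.83 without ELS-HFD 4 to -0.30 without ELS-HFD 3, and Bdnf from -0.45 without ELS-HFD 4 to -0.03 without HFD 4. Fkbp5 ranged from -0.22 without HFD 2 to 0 without HFD 4, and Dnmt3a from -0.10 without ELS-HFD 2 to 0.07 without ELS-HFD 3. Oxtr was at -0.72 without ELS-HFD 2, and Lepr at 0.19 without ELS-HFD 3 and 0.48 without HFD 2. All 23 cholesterol biosynthesis genes were negative (adjusted p = 1.95e-05, and adjusted p = 0.777 with an estimated correlation), with Hsd17b7 at -0.27 ± 0.12 and Stard4 at -0.23 ± 0.11. All 20 heat shock and unfolded protein genes were negative as well (adjusted p = 0.00118, and adjusted p = 0.777 with an estimated correlation), with a mean log2 fold of -0.10.

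Interferon and MHC genes (adjusted p = 0.000133), nuclear oxidative phosphorylation genes (adjusted p = 0.00288) and hypothalamus genes (adjusted p = 0.0306) were called lower, each with adjusted p = 0.777 with an estimated correlation, and Rsad2 was at -0.86 ± 0.35, or -0.47 without HFD 2. Microglial genes (adjusted p = 0.0306) and fibroblast genes of the meninges (adjusted p = 0.0312) were called higher, with Aif1 at 0.30 ± 0.13 and decorin (Dcn) at 0.92 ± 0.41, or 0.53 without ELS-HFD 2. Lower calls for myelin (adjusted p = 0.0306), ependymal (adjusted p = 0.0342) and choroid plexus genes (adjusted p = 0.0306) also had, like the microglial and meningeal lists, adjusted p = 0.777 with an estimated correlation. The choroid plexus genes had a mean log2 fold of 0.04 in edgeR, opposite in sign to their call. Without ELS-HFD 1 the myelin, ependymal and choroid plexus calls reversed their sign (adjusted p = 0.927, 0.523 and 0.157). The number of lists called was 5 without HFD 3 and 6 without ELS-HFD 1. Only the neuropeptide, central amygdala and cholesterol lists were called in every fit that left out 1 library. Without ELS-HFD 1 the microglial, heat shock, hypothalamus and stress axis calls ended (adjusted p = 0.582, 0.375, 0.183 and 0.0926), without HFD 1 the oxidative phosphorylation and interferon calls (0.379 and 0.0677), and without HFD 2 the meningeal call (0.26).

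Averaged over both rearings, the high fat diet was compared with chow over 8 libraries each. Samd4a fell by 0.65 ± 0.07 on the log2 scale (edgeR adjusted p = 0.000647), and all 8 high fat libraries lay below all 8 chow libraries. The difference was -0.58 ± 0.09 after undisturbed rearing and -0.72 ± 0.09 after separation, in libraries that do not overlap, and the interaction of Samd4a was -0.14 ± 0.13 (adjusted p = 1). No other gene passed in edgeR, 787 had an unadjusted p under 0.05, and DESeq2 called 2, Samd4a and Lonrf1. Lonrf1 was at 0.43 ± 0.08 (edgeR adjusted p = 0.387). With adjusted p = 0.824 followed Smad7 at -0.23 ± 0.05, Trim16 at -0.50 ± 0.11, Jph1 at 0.37 ± 0.09, Sox10 at -0.44 ± 0.10 and Npy1r, a receptor for neuropeptide Y, at 0.38 ± 0.09. Among libraries whose code ends in N, 6 on chow and 3 on high fat diet, Samd4a differed by -0.75, and among those ending in B, 2 on chow and 5 on high fat diet, by -0.53. The labels do not say what the letters mean.

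**Figure D3:**
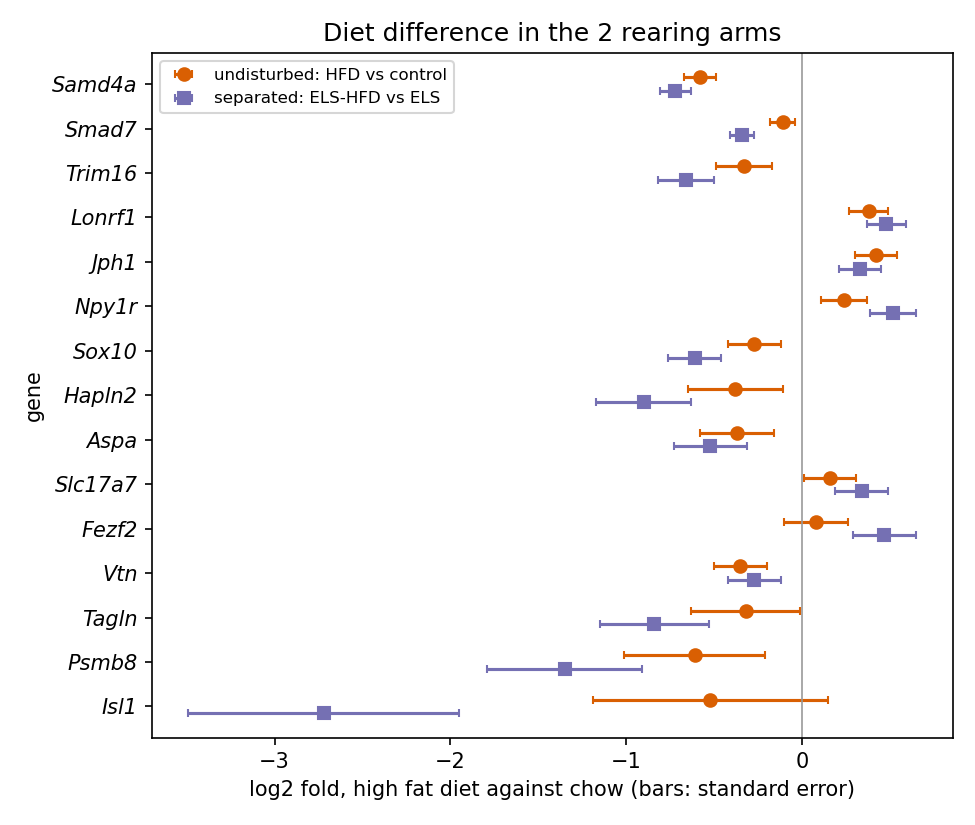
Log2 fold of high fat diet against chow for 15 named genes of the diet contrast, after undisturbed rearing (circles, HFD against control) and after separation (squares, ELS-HFD against ELS), with bars for the SE. Samd4a lay at -0.58 and -0.72, and Isl1 was furthest apart at -0.52 ± 0.67 and -2.72 ± 0.77.

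Camera with the preset correlation called 8 lists for diet, 1 higher and 7 lower, none with an estimated correlation or by fry. No member of a list passed over all genes, and 25 passed adjusted over the list alone, of which 19 were among the 21 myelin genes. All 21 were negative (adjusted p = 9.18e-17, and adjusted p = 0.531 with an estimated correlation), with a mean log2 fold of -0.50, Hapln2 at -0.64 ± 0.19 and Aspa at -0.44 ± 0.15. ELS 3 and ELS 4 stood apart on this list at 1.08 and 0.90, and without them Hapln2 was at -0.29 and Sox10 at -0.26. The diet difference in the myelin list level, -0.46, had an exact permutation p = 0.08, two-sided over 4900 arrangements within rearing. Oligodendrocyte precursor genes were called lower (adjusted p = 0.00494), and had adjusted p = 0.579 with an estimated correlation. Pericyte and smooth muscle genes were called lower (adjusted p = 0.00177, and adjusted p = 0.531 with an estimated correlation), with Vtn at -0.31 ± 0.11 and Tagln at -0.58 ± 0.22, and at -0.19 and -0.26 without ELS 3 and ELS 4. Endothelial genes (adjusted p = 0.0275), central amygdala genes (adjusted p = 0.00472) and interferon and MHC genes (adjusted p = 0.00641) were called lower, each with adjusted p = 0.769 with an estimated correlation. In these lists Isl1 was at -1.62 ± 0.51 and Psmb8 at -0.98 ± 0.30. Striatal genes were called lower (adjusted p = 0.0222, and adjusted p = 0.925 with an estimated correlation). Excitatory neuron genes were called higher (adjusted p = 0.00439, and adjusted p = 0.609 with an estimated correlation), with 12 of 13 positive, Slc17a7 at 0.25 ± 0.11 and Fezf2 at 0.28 ± 0.13. Only the myelin and pericyte lists were called in every fit that left out 1 library. Without control 4 the endothelium and precursor calls ended (adjusted p = 0.562 and 0.111), without control 3 the central amygdala call (0.116), without ELS 3 the striatal and excitatory neuron calls (0.309 and 0.0633) and without ELS-HFD 4 the interferon call (0.102). The count of genes past the test was 49 with the choroid plexus level as a covariate, 21 with the striatum level added, and 102 without ELS 1, ELS 2 and ELS-HFD 1, all chosen after seeing the data.

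Averaged over both diets, separation was compared with undisturbed rearing. Mme had the smallest p at 0.54 ± 0.11, with all 8 separated libraries above all 8 undisturbed ones, at 4.36 ± 0.771 and 4.00 ± 0.435 CPM in ELS and ELS-HFD against 2.86 ± 0.340 and 2.90 ± 0.355 CPM in control and HFD. Mme was named for the smallest p of 14208 genes, and how many genes separate this fully was not counted. Its separation is therefore no further support. The phosphatase Ctdspl2 was at 0.62 ± 0.14 and the polo-like kinase Plk5 at 0.85 ± 0.21. Galns was at -0.29 ± 0.08, the retinol dehydrogenase Rdh13 at -0.23 ± 0.07 and RT1-N2 at -3.36 ± 0.88, the last uncertain as before. RT1-N2 was at -2.20 without HFD 1 and at -5.59 without ELS-HFD 3. No gene passed in edgeR (smallest adjusted p = 1), 370 had an unadjusted p under 0.05, and DESeq2 called 0. Of the panel, Crh was at -0.46 ± 0.27, Crhr1 at -0.12 ± 0.21, Oxtr at -0.34 ± 0.20, Fkbp5 at -0.06 ± 0.08, Lepr at 0.49 ± 0.48, Bdnf at 0.07 ± 0.15 and Dnmt3a at 0.06 ± 0.07, each with edgeR adjusted p = 1. Leaving out 1 library turned the sign of Bdnf, which ranged from -0.07 without ELS-HFD 4 to 0.14 without ELS-HFD 1 or HFD 4, and of Fkbp5, at 0.01 without HFD 4. Crhr1 ranged from -0.30 without ELS-HFD 4 to -0.04 without control 3 or ELS-HFD 3, with Dnmt3a at 0.11 without ELS-HFD 3, and Lepr at 0.21 without ELS-HFD 3, 0.27 without ELS 4 and 0.30 without ELS 3.

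For separation, camera with the preset correlation called 12 lists, 3 higher and 9 lower. Each of the 12 had adjusted p = 0.645 with an estimated correlation, fry called none, and no member passed over all genes or adjusted over the list alone. Genes of energy and sterol metabolism were called lower. Of 63 nuclear oxidative phosphorylation genes 57 were negative (adjusted p = 4.35e-07, and adjusted p = 0.645 with an estimated correlation), with Ndufb3 at -0.11 ± 0.04, and of 12 mitochondrially encoded genes 11 were negative (adjusted p = 0.001, and adjusted p = 0.645 with an estimated correlation), with Mt-co2 at -0.22 ± 0.09. Of 23 cholesterol biosynthesis genes 22 were negative (adjusted p = 4.63e-05, and adjusted p = 0.645 with an estimated correlation), with the isomerase Idi1 at -0.22 ± 0.09. Interferon and MHC genes (adjusted p = 2.79e-05), heat shock genes (adjusted p = 0.0123), the stress axis list (adjusted p = 0.0223) and hypothalamus genes (adjusted p = 0.00882) were also called lower, each with adjusted p = 0.645 with an estimated correlation. Rsad2 was at -0.80 ± 0.25 and Irf9 at -0.21 ± 0.07. Microglial genes were called higher (adjusted p = 0.00039), with 14 of 17 positive, as were striatal genes (adjusted p = 0.000379) and circadian clock genes (adjusted p = 0.012), each with adjusted p = 0.645 with an estimated correlation. Cx3cr1 was at 0.21 ± 0.06, the microglial receptor Gpr34 at 0.19 ± 0.08 and Pde1b at 0.34 ± 0.15. Ependymal genes (adjusted p = 0.00974) and choroid plexus genes (adjusted p = 0.000444) were called lower, both with adjusted p = 0.645 with an estimated correlation, while the choroid plexus genes had a mean log2 fold of 0.11 in edgeR. Only the nuclear oxidative phosphorylation, cholesterol, interferon and microglial lists were called in every fit that left out 1 library. The mitochondrial call ended without control 4 (adjusted p = 0.133), the heat shock call without control 1 (0.424), the stress axis call without ELS 4 (0.12), the hypothalamus call without control 3 (0.0793), the striatal and clock calls without ELS-HFD 4 (0.0759 and 0.132), the ependymal call without ELS-HFD 1 (0.352) and the choroid plexus call without ELS 2 (0.263).

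The separation-by-diet interaction is the diet difference after separation minus that after undisturbed rearing. Hsf2, a heat shock transcription factor, had the smallest p, with a difference of 0.37 ± 0.09 on the log2 scale, at 36.8 ± 0.851 CPM in control, 34.4 ± 1.47 CPM in HFD, 32.5 ± 2.88 CPM in ELS and 39.2 ± 1.76 CPM in ELS-HFD. Plekhg6 was at 1.16 ± 0.30 and Ly6l at 1.77 ± 0.46. On the negative side were the NF-kappaB subunit gene Relb at -0.78 ± 0.21, Tango6 at -0.43 ± 0.13 and Nol12 at -0.43 ± 0.13. No gene passed in edgeR (smallest adjusted p = 1), 317 had an unadjusted p under 0.05, and DESeq2 called 0. Simulated differences of 1.5-fold were recovered at 25% in this contrast.

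Camera with the preset correlation called 8 lists for the interaction, 3 higher and 5 lower, none with an estimated correlation or by fry, and no member passed over all genes or adjusted over the list alone. Central amygdala genes were more negative after separation (adjusted p = 2.56e-07, and adjusted p = 0.537 with an estimated correlation), with Isl1 at -2.21 ± 1.03, Nts at -1.52 ± 0.60, Pdyn at -1.43 ± 0.66 and Crh at -1.32 ± 0.55. Neuropeptide genes (adjusted p = 0.000534) and immediate early genes (adjusted p = 0.00656) were called in the same direction, each with adjusted p = 0.814 with an estimated correlation, and Egr4 and Egr1 were at -0.77 ± 0.32 and -0.62 ± 0.29, with Egr4 at -0.51 without HFD 4. Myelin genes (adjusted p = 5.44e-07), with Mag at -0.66 ± 0.36, and striatal genes (adjusted p = 0.000168) were called lower, both with adjusted p = 0.883 with an estimated correlation. ELS 3 and ELS 4 carried the high levels of the ELS group, at 1.08 and 0.90 for myelin and 1.18 and 0.55 for striatal genes, and without them Mag was at -0.02. Cytosolic ribosomal protein genes (adjusted p = 0.00531) and astrocyte genes (adjusted p = 0.00978) were called higher, again with adjusted p = 0.883 with an estimated correlation. Red cell genes were called higher (adjusted p = 0.000255, and adjusted p = 0.537 with an estimated correlation), with Alas2 at 1.00 ± 0.49. The number of lists called was 5 without HFD 4, 14 without ELS 3, and 13 without control 1, control 2 or HFD 1. The ribosomal call ended without ELS-HFD 1 (adjusted p = 0.494), the astrocyte call without control 4 (0.493) and the immediate early call without ELS 4 (0.113). Across 11750 genes with a mean count of at least 50, the diet differences of the 2 rearing arms, which share no library, had a Pearson correlation of 0.2. The separation differences of the 2 diet arms had one of 0.042. Genes are not independent replicates, so neither correlation carries a p-value.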

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

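The tests of explanations and of other splits of the samples were chosen after the results they bear on were seen, while the search for libraries that stand apart and the test of the interaction were planned.

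Samd4a was lower in all 8 high fat libraries than in all 8 chow libraries. Differing shares of choroid plexus and striatal tissue are argued against as the whole cause, since with both list levels as covariates the diet difference passed at adjusted p = 0.00333. The letter at the end of the library code is argued against in the same way, at adjusted p = 0.00463 with the letter as a covariate. The high fat diet stays open as a hypothesis without a test of its own: the exact permutation p = 0.0286 in the undisturbed arm, the smallest that 4 against 4 allow, follows from the pattern itself and decides nothing. Reads of an antisense transcript were not tested, so the difference may lie in a transcript other than the messenger RNA of Samd4a.

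Choroid plexus transcripts were low in ELS 1, ELS 2 and ELS-HFD 1, at -2.38, -4.87 and -4.93. The 17 members of the list moved together, with a median correlation of each member with the rest of the list of 0.989 over the 16 libraries and a lowest one of 0.908. Differing amounts of choroid plexus tissue taken up with the sample would give this. So would any cause that moves the list as a whole. The correlations also include the 3 low libraries, so the pattern itself makes them high and they cannot decide the cause. The next most coherent list, myelin, had a median of 0.968. All 3 low libraries were from separated males, but of the 8 separated libraries 4 lay within the range of the undisturbed ones and 1, ELS 3, above it. The difference of -1.2 between separated and undisturbed libraries had an exact permutation p = 0.329, two-sided over 4900 arrangements within diet, so that an effect of maternal separation may be present or absent.

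Myelin genes were lower in ELS-HFD than in ELS, with a difference in list level of -0.68 ± 0.33 (SE). With the choroid plexus level as a covariate the difference was -0.75 ± 0.15. Choroid plexus and myelin levels rose together within groups (r = 0.90). The choroid plexus level was -0.41 ± 3.11 in ELS-HFD and -0.79 ± 3.42 in ELS, so this covariate could only enlarge the difference. The measured choroid plexus level thus did not account for the lower myelin level, and the value decides nothing on dissection in other respects. White matter in ELS 3 and ELS 4 remains a possible explanation, since without these 2 libraries the difference was -0.05 ± 0.27. They were picked because they show the pattern, so that this value cannot decide. The high fat diet is open too, with a difference of -0.23 and an exact permutation p = 0.0857, two-sided over 70 arrangements, in the undisturbed arm.

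Splits of the same libraries, the real one counted among them, were tested with the same fit, all 35 for each pairwise contrast and 100 drawn for each of the others. Chance could not be excluded for the gene counts of ELS-HFD against ELS and of diet, or for any count of lists. For genes, 4 of 35 splits gave as many calls as the 1 of ELS-HFD against ELS, with 1898 as the highest other. For diet, 12 of 100 drawn splits gave as many as its 1 call, with 877 as the highest other. These counts take any gene, so they are no test of Samd4a itself. Some drawn diet splits with a call also kept all 4 ELS-HFD libraries on 1 side, as the real split does. The real count was 0 in the remaining contrasts, so that all 35 or all 100 splits gave as many by construction and the splits decide nothing there. The highest others there were 1 for HFD against control, 1486 for ELS against control, 25 for ELS-HFD against control, 1 for ELS-HFD against HFD, 1163 for separation and 166 for the interaction. A split that calls many genes points to a structure of the samples. The 1486 came from control 1, control 4, ELS 3 and ELS 4 against the rest, and the 1898 from ELS 1, ELS 2, ELS-HFD 1 and ELS-HFD 4 against the rest. Both splits divided their libraries by choroid plexus level. In the first, the named libraries lay at 0.79 or higher on that list and the rest at -0.14 or lower. In the second, the named libraries lay at 0.13 or lower and the rest at 1.16 or higher. Genes with an unadjusted edgeR p under 0.05 numbered 882 in the real split of ELS-HFD against ELS and 4007 in that second split. For diet they numbered 787 in the real split and up to 3465 in another drawn split. The real counts of 882 and 787 therefore show no excess over other splits. For lists, the splits with as many calls numbered 22 of 35 for HFD against control (real 11, highest other 16), 21 of 35 for ELS against control (13 and 19), 30 of 35 for ELS-HFD against control (9 and 18), 26 of 35 for ELS-HFD against ELS (9 and 17) and 4 of 35 for ELS-HFD against HFD (13 and 15). Of 100 drawn splits they numbered 82 for diet (8 and 19), 43 for separation (12 and 20) and 85 for the interaction (8 and 20).

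The diet difference of 8 lists differed between the rearing arms by the test of the interaction with the preset correlation. More negative after separation were central amygdala genes (adjusted p = 2.56e-07), myelin genes (adjusted p = 5.44e-07), striatal genes (adjusted p = 0.000168), neuropeptide genes (adjusted p = 0.000534) and immediate early genes (adjusted p = 0.00656). More positive after separation were red cell genes (adjusted p = 0.000255), cytosolic ribosomal protein genes (adjusted p = 0.00531) and astrocyte genes (adjusted p = 0.00978). None was called with an estimated correlation, where the smallest adjusted p was 0.537.

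A library stood apart from the other 3 of its group in 36 of 556 sets of values examined, where chance gives about 1 in 20, or 28. Total counts were 21.7 M (21716366 in full) in control 2 against 12.4 M to 14.0 M in the other controls. Among lists, heat shock genes were at -0.36 in ELS-HFD 1, microglial genes at 0.29 in ELS 3 and red cell genes at 0.6 in HFD 1. Single genes are given as log2 CPM. In control libraries these were Gja1 at 9.59, Myrf at 6.77, Cartpt at 3.27 and Bdnf at 4.24 in control 4, the last pair below the other controls, and Adamts9 at 2.18 in control 1. In the HFD group, HFD 1 was high for Hapln2 at 4.96 and Psmb8 at 1.57, HFD 2 was low for Sema3e at 3.55 and Neurod1 at 2.70, HFD 3 was high for Gjb6 at 5.77, and HFD 4 was high for Ppp1r1b at 8.14. In the ELS group, ELS 3 was high for Pde1b at 7.87, Rasd2 at 7.86 and Rsad2 at 1.33 and low for Slc17a7 at 9.95 and Spg7 at 5.84. ELS 4 was low for Tfap4 at 2.40 and high for Sema3e at 4.05, ELS 1 was low for Ciart at 3.31 and high for Crhr1 at 3.61, and ELS 2 was high for Cx3cr1 at 4.91 and low for Nol12 at 3.04. In the ELS-HFD group, ELS-HFD 1 was high for Adamts9 at 2.99 and low for Ctdspl2 at 4.24 and Trim16 at 1.38, and ELS-HFD 2 was high for Galns at 3.54. ELS-HFD 3 was high for Lpcat3 at 4.86, Sdhaf3 at 2.87 and RT1-N2 at -0.17 and low for Stard4 at 3.21, and ELS-HFD 4 was high for Rasd2 at 7.60 and low for Tagln at 3.19.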

How the results depend on the processing

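The covariates of list levels and the fits without the 3 libraries with the fewest choroid plexus transcripts or the 2 with the most myelin transcripts were chosen after seeing the data, and the other alternatives were planned. Samd4a passed in the diet contrast under each of 26 alternatives, with adjusted p from 1.75e-13 by DESeq2 to 0.0081. Scaling by DESeq2 size factors, both other filters and the code letter left the counts of genes past the test at 1 for ELS-HFD against ELS and diet and at 0 for the other 6 contrasts. A fit of only 8 libraries cannot be made for the averaged contrasts and the interaction. No list was called with an estimated correlation (0 in all 8 contrasts) or by fry (0 in all 8 contrasts). Of the lists called, those called in every fit that left out 1 library numbered 1 of 11 for HFD against control, 3 of 13 for ELS against control, 2 of 9 for ELS-HFD against control, 3 of 9 for ELS-HFD against ELS, 3 of 13 for ELS-HFD against HFD, 2 of 8 for diet, 4 of 12 for separation and 5 of 8 for the interaction. The causes of the differences listed next were not tested, beyond the smaller number of libraries in some fits. Counts per library ranged from 11 to 235 for Gal and from 2 to 110 for Isl1. In control, Gal had 54, 235, 124 and 20 counts, while total counts ran from 12.4 M to 21.7 M. These Gal counts spread more widely than the totals, which argues against depth alone behind the error of its fold. For Isl1, with as few as 2 counts in a library, depth and spread between libraries were not told apart.

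Replicate numbers did not pair the samples: of 24 pairs with the same number, 8 had a correlation of deviations over 0.1, the range was -0.48 to 0.65, and 5 of 16 libraries correlated best with one of their own number. The samples share only a number, and with it as a block the counts of genes were 1 for ELS-HFD against ELS (Samd4a adjusted p = 0.0204), 1 for diet (Samd4a adjusted p = 0.00145) and 0 for the other 6 contrasts.

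DESeq2 called 1 gene for HFD against control, 2 for ELS-HFD against control, 5 for ELS-HFD against ELS and 2 for diet. With the choroid plexus level as a covariate edgeR called 58 for ELS-HFD against ELS and 49 for diet, and with the striatum level added 2 and 21. Without the 3 libraries with the fewest choroid plexus transcripts the counts were 116 for ELS-HFD against ELS, 102 for diet and 23 for ELS against control. In that fit the ELS group held only ELS 3 and ELS 4, the libraries highest on the myelin list. For ELS-HFD against ELS the count was 0 without the 2 libraries with the most myelin transcripts and 0 with only the 8 libraries.

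Without those 2 libraries the log2 fold turned to -0.17 for Mog, -0.04 for Ppp1r1b and -0.02 for Sox10 in ELS against control and to -0.58 for Lepr in the separation contrast. With both list levels as covariates that of Bdnf for separation was -0.10. None of these genes passed in the fits just named. Mog and Sox10 each passed for ELS against control in 1 of the alternatives (edgeR adjusted p = 0.0309 each). It was the fit without the 3 libraries with the fewest choroid plexus transcripts, chosen after seeing the data. That fit left only ELS 3 and ELS 4, the libraries highest on the myelin list, in the ELS group. In fits that left out 1 library, the log2 fold of Bdnf for separation ranged from -0.07 without ELS-HFD 4 to 0.14 without ELS-HFD 1, of Fkbp5 for separation from -0.09 without control 3 to 0.01 without HFD 4, of Fkbp5 for ELS-HFD against HFD from -0.22 without HFD 2 to 0 without HFD 4, and of Dnmt3a for ELS-HFD against HFD from -0.10 without ELS-HFD 2 to 0.07 without ELS-HFD 3.

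When 1 library was left out, the count of genes ranged from 0 to 1 for ELS-HFD against control (1 without ELS-HFD 3) and from 0 to 1 for ELS-HFD against ELS. Lists called ranged from 3 without HFD 4 to 16 without HFD 1 for HFD against control, from 5 without control 3 to 14 without control 2 for ELS-HFD against control, from 9 without ELS 2 to 16 without ELS 1 for ELS-HFD against ELS, from 5 without HFD 3 to 12 without ELS-HFD 3 for ELS-HFD against HFD, and from 5 without HFD 4 to 14 without ELS 3 for the interaction. The adjusted p of lists that reversed ranged as follows. Choroid plexus genes went from 2.41e-06 without ELS 3 to 0.92 without ELS 2 in ELS against control, and from 0.00105 without ELS-HFD 3 to 0.541 without HFD 1 in ELS-HFD against HFD. In the latter contrast ependymal genes went from 2.17e-05 without ELS-HFD 3 to 0.523 without ELS-HFD 1, and myelin genes from 8.17e-07 to 0.927 without the same libraries. Fatty acid genes in HFD against control went from 0.00218 without control 2 to 0.727 without control 4, and mitochondrially encoded genes in ELS-HFD against control from 8.59e-05 without control 1 to 0.958 without control 4.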

Other observations

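The correlations between list levels and the cholinergic list were chosen after the data were seen, and the lists in the next paragraph were planned.

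Of the 36 lists, 10 were called in none of the 8 contrasts by camera with the preset correlation. Genes of DNA methylation and chromatin, 23 measured, had adjusted p from 0.056 to 0.83 over the 8 contrasts, and inflammation genes, 16 measured, from 0.0638 to 0.853. The glucocorticoid response list, 18 genes, ranged from 0.0831 to 0.991 and the feeding, leptin and insulin list, 22 genes, from 0.303 to 0.908. Transmission genes were in the same position, with GABA at 0.0912 to 0.767, glutamate at 0.124 to 0.713 and monoamine receptors at 0.361 to 0.95. The inhibitory neuron list ranged from 0.124 to 0.771. Markers of neighbouring regions ranged from 0.0963 to 0.776 for the thalamus and from 0.364 to 0.92 for the hippocampus.

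Within groups, list levels moved together over the 16 libraries, taken as deviations from group means in a family of 4 relations with 100000 permutations each. The permutations shuffled deviations over all 16 libraries and not within groups. Spread differed between groups, with a choroid plexus SD of 3.42 in ELS and 0.93 in HFD. The deviations are therefore not fully exchangeable, and the permutation p-values are approximate. Choroid plexus and ependymal levels had Pearson r = 0.95 (permutation p = 1e-05, the smallest these permutations can give, adjusted 2.7e-05) and Spearman rho = 0.93 (p = 1e-05), with r = 0.93 without ELS-HFD 1 and ELS 2. Choroid plexus and myelin levels had r = 0.90 (permutation p = 2e-05, adjusted 2.7e-05) and rho = 0.89 (p = 3e-05), with r = 0.86 without the same libraries. Within code letters this r was 0.87 in 9 N libraries and 0.96 in 7 B libraries, and that of choroid plexus and ependymal levels 0.93 and 0.96. Striatal and cholinergic levels had r = 0.85 (permutation p = 2e-05, adjusted 2.7e-05) and rho = 0.86 (p = 3e-05), with r = 0.85 without ELS-HFD 4 and control 4, 0.81 in N and 0.84 in B libraries. Cholinergic and myelin levels had r = 0.60 (permutation p = 0.01, adjusted 0.01) but rho = 0.34 (p = 0.2), with r = 0.59 without ELS 3 and control 4, 0.75 in N and 0.37 in B libraries.

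RT1-N2, an MHC class I gene that has near copies and is uncertain for that reason, had raw counts of 171, 256, 101 and 83 in control, 170, 21, 23 and 0 in HFD, 15, 70, 10 and 11 in ELS, and 0, 0, 10 and 0 in ELS-HFD. Samd4b, the paralog of Samd4a, had a diet log2 fold of -0.04 ± 0.06 (edgeR unadjusted p = 0.554), against -0.65 ± 0.07 (edgeR unadjusted p = 4.56e-08) for Samd4a in the same fit.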
